A study of Mus musculus with 16 samples.

How the data were processed

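Total RNA from bone marrow of 16 mice was labelled with Cy3 and hybridised to 1-colour Agilent mouse arrays, 1 array per mouse, 8 KO chimeras and 8 controls, per the labels' protocols. Groups and replicate numbers came from the sample titles. Scanner images were quantified with Agilent Feature Extraction 10.7 per the submitters' processing notes and 10.1.1.1 per the file headers. The deposited scanner files give spot intensity on a linear scale, background-subtracted by the scanner software, per the file headers. The authors' processed value table, with 59305 rows, holds log2 values whose row numbers match the spot numbers; each column correlated with the log2 scanner signal of its array at r = 0.991 or more. Its lowest value was 2.3, at which 24.3% to 24.8% of each column lay, and the descriptions in the labels point to quantile normalization. Its column medians were 5.00, 5.00, 5.00, 5.00, 5.00, 5.00, 5.00, 5.00 for controls 1 to 8 and 4.99, 4.98, 5.00, 5.00, 5.00, 4.99, 4.99, 5.00 for KO chimeras 1 to 8; scale and direction follow from the match, and how it was centred is not given in the sources used here.

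Processed signals were divided by the array's 75th percentile over non-control spots and taken to log2. Spots called outliers by the scanner software were left out, spots of a probe were averaged, and no spot was saturated. Of 55681 probes, 32693 were well above background on at least 6 of the 8 arrays of either group and were kept. Each gene name was read from its brightest kept probe, which gave 23060 gene names with at least 3 values per group; 4 had too few. Names are those of the array design, updated through RefSeq accessions of the reference table (GRCm38.p6, used for names only), which matched 14410 genes; probe positions are those of the files (mm9), and no annotation of exons in that build was used here. A gene symbol was taken to be a name in that table or one with a curated RefSeq accession.

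Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, call at adjusted p under 0.05). Differences are KO chimera minus control on the log2 scale with the SE of the fit. Where no array of a group was well above background, the fold is a bound: the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. Gene lists (32 lists covering receptors, signalling, clock, marrow cell types, stroma, stress and inflammation, housekeeping, sex and strain) were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Named genes were, by a rule fixed before the data were examined, Adrb1, the 12 largest increases and 12 largest decreases among changed gene symbols, up to 3 changed members per list by smallest p (or the 2 smallest p where none passed), and every measured sex-linked and strain-dependent gene; 2 genes that the rule names are not reported here.

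The test was checked on simulated data for the KO chimera against control comparison over 22291 genes with values on every array, drawn independently with the real means and spreads. Of 50 genes changed by 0.5 (log2), 22 of 50 were recovered, 47 of 50 at 1, 49 of 50 at 2 and 40 of 50 at -1, with 8 false calls, and 0 calls were made when no gene was changed. A list shifted by 1 was called, and 0 lists that were not shifted were. As genes were drawn independently, this does not check the list test on lists whose members vary together.

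Alternatives were quantile normalization, normexp background correction on the mean and background signals with quantile normalization, the authors' values, other filters on dim probes, slide, scan day and replicate number as blocks, slides holding both groups alone, the mean of a gene's probes, a test per probe, array weights, a variance trend, leaving out each mouse, other thresholds and other set tests. The brightness of the array as a covariate and fits within each scan day were added after seeing the data. Arrays lay on 6 slides, 5 of which held both groups, and were scanned on 2 days with 4 mice of each group per day. Labels describe each sample as a separate mouse.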

Results

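Gene expression was measured in the bone marrow of 16 mice on 1-colour arrays, 8 mice in each of 2 groups. KO chimeras were C57BL/6J mice that received marrow from donors lacking beta adrenergic receptors, through which noradrenaline from sympathetic nerves acts on many cells, after 950 rad of irradiation and 2 to 3 months of recovery. Controls were C57BL/6J mice with the same 950 rad of irradiation and 2 to 3 months of recovery. The labels name no donor for them. The comparison is of knockout marrow grafts with these controls, and it does not separate receptor loss from the donors' genetic background or from grafting itself. The 75th percentile of the processed signal ran from 127 to 545 in KO chimeras and from 231 to 558 in controls (exact two-sided permutation p = 0.301, n = 8 mice per group). Between 27755 and 37087 probes were well above background in KO chimeras and between 29292 and 38743 in controls (exact two-sided permutation p = 0.0692, n = 8 per group). The number of mice limits the precision of every value.

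The targeted gene Adrb1 did not fall in marrow of the KO chimeras. It was level between groups, with a log2 difference (KO chimera minus control) of -0.00041 ± 0.11 (SE, n = 8 mice per group, adjusted p = 0.999). Its probe lies on chromosome 19, 56797242 to 56797301 of mouse build mm9. A dimmer Adrb1 probe, on chromosome 19, 56799215 to 56799274, was above background on 6 control and 7 KO chimera arrays and differed by 0.95 (exact two-sided permutation p = 0.00824, n = 8 per group). Where these probes lie relative to the deleted part of the gene is not given in the sources used here, so they do not check the genotype. Adrb3 rose by 0.58 ± 0.11 (adjusted p = 9.69e-04). Of the adrenergic receptor list, 2 of 5 measured members rose, 0 fell and 3 did not pass (2 up and 0 down adjusted over the list alone). The receptor median was 0.24 (camera adjusted p = 0.0418, adjusted p = 0.386 with an estimated correlation).

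**Figure D1:**
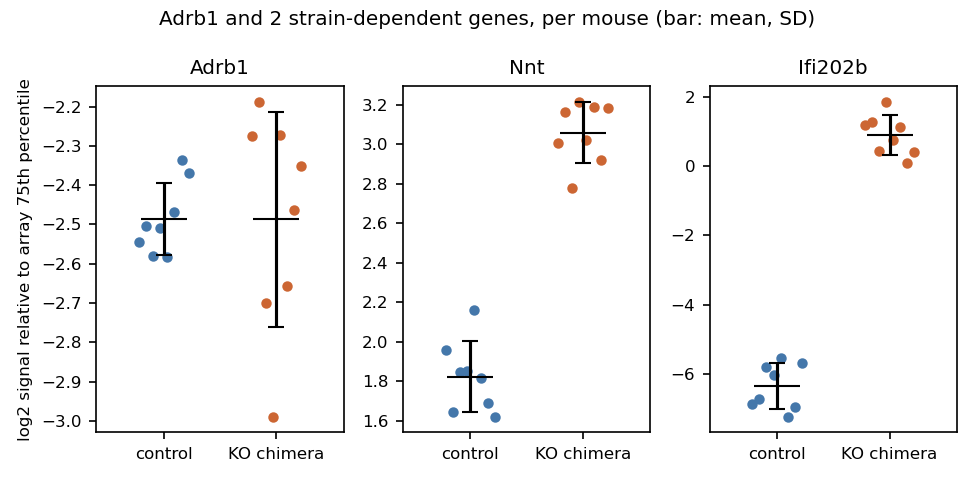
Signal of Adrb1, Nnt and Ifi202b in each mouse, as log2 relative to the array's 75th percentile, with controls on the left and KO chimeras on the right of each panel; points are mice and bars are the mean with SD (n = 8 per group). Adrb1 overlaps between groups, whereas Ifi202b, above background on no control array, does not.

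Marrow of the KO chimeras differed from control marrow in 5140 of 23060 genes tested, 2360 higher and 2780 lower (limma, Benjamini-Hochberg adjusted p under 0.05). The largest differences were near on or off. H60a, which encodes a ligand of the NK cell receptor NKG2D, was not well above background on any control array and at least 107-fold higher in KO chimeras (adjusted p = 2.65e-13), and the interferon-inducible gene Ifi202b was at least 60.4-fold higher (adjusted p = 1.38e-11). In the other direction Vill fell by 6.72 ± 0.53 and Pnp2, a purine nucleoside phosphorylase, fell by 6.54 ± 0.56 on the log2 scale (adjusted p = 7.3e-08 and 1.88e-07), although Pnp2 was above background on only 1 KO chimera array, so that its size and rank are approximate. Most changes were small, with a median absolute log2 difference of 0.59 among changed genes; 105 genes rose and 134 fell by more than 2. The 8 KO values did not overlap the 8 control values for 1415 genes, 6.14% of those tested, against 0.0155% by chance. Within scan day 1 (4 mice against 4) 1612 genes changed and within scan day 2 2314. Of these, 99.4% and 98.1% had the same direction in the mice of the other day, where 50% would be expected with no difference. Over all genes tested, changed or not, the share was 76.1% for each day. With slide as a block 4825 genes changed and with scan day as a block 5579. Of genes called with 1 of the 5 slides holding both groups left out, 88.3% to 97.6% had the same direction on that slide. Over all genes tested this share was 65.9% to 75.4% (checks on mice left out were chosen after the results were seen).

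Among the 12 largest increases, 6 genes were above background on no control array and have only a lower bound: H60a and Ifi202b above, Jhy (named 4931429I11Rik on the array) at least 25.8-fold, Col6a4 at least 17.8-fold, Pawr at least 10.6-fold and Itlnb at least 9.2-fold. Itln1, which encodes a secreted lectin, was above background on 1 control array and rose by 7.13 ± 0.22, St6galnac2 (a sialyltransferase, 2 control arrays) by 6.48 ± 0.13 and Cstdc6 (BC117090 on the array, 1 control array) by 6.32 ± 0.30; sizes and ranks of these 3 are approximate, as the control signal lay mostly near background. Above background on every array of both groups, BC018473 rose by 5.71 ± 0.14 (7 control values, 1 outlier spot left out), Gdpd3 by 5.44 ± 0.18 and Stab2, a scavenger receptor of sinusoidal endothelium, by 4.99 ± 0.22. BC018473 and St6galnac2 lie close together, with probes on chromosome 11, 116619134 to 116619193 and chromosome 11, 116538040 to 116538094 (mm9). The files place the H60a and Itlnb probes nowhere on mm9. Adjusted p was 1.1e-07 or less for these 12 genes.

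Among the 12 largest decreases, Snhg12 (a small nucleolar RNA host gene) fell to a log2 difference of -6.45 ± 0.50, Klra2 (a receptor gene of the Ly49 family) -6.44 ± 0.58, Redrum -5.59 ± 0.50, Olfml2b -4.95 ± 0.44, Psg16 -4.58 ± 0.40 (but -0.14 on a second probe, which did not pass) and 2610507I01Rik -4.55 ± 0.30. Rnase12 differed by -4.53 ± 0.26, Skint3 by -4.24 ± 0.49, Ms4a8a by -3.80 ± 0.35 and Oasl2, an interferon-inducible gene, by -3.79 ± 0.33 (adjusted p 7.44e-06 or less). All 12 were above background on 8 control arrays, and Pnp2 and Klra2 on only 1 KO chimera array each, Olfml2b and Rnase12 on 2, Redrum and Skint3 on 3, Ms4a8a on 5, Snhg12 on 6 and Vill on 7. Sizes and ranks of Pnp2, Klra2, Olfml2b, Rnase12, Redrum and Skint3 are thus approximate. Among the KO chimeras, number 7 lay nearest to the controls for 11 of these 12 genes and for 8 of the 12 largest increases. H60a, Itln1, Itlnb, Ifi202b, Klra2, Psg16, Pnp2 and Oasl2 belong to families of similar genes, so a probe can also read a close relative.

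**Figure D2:**
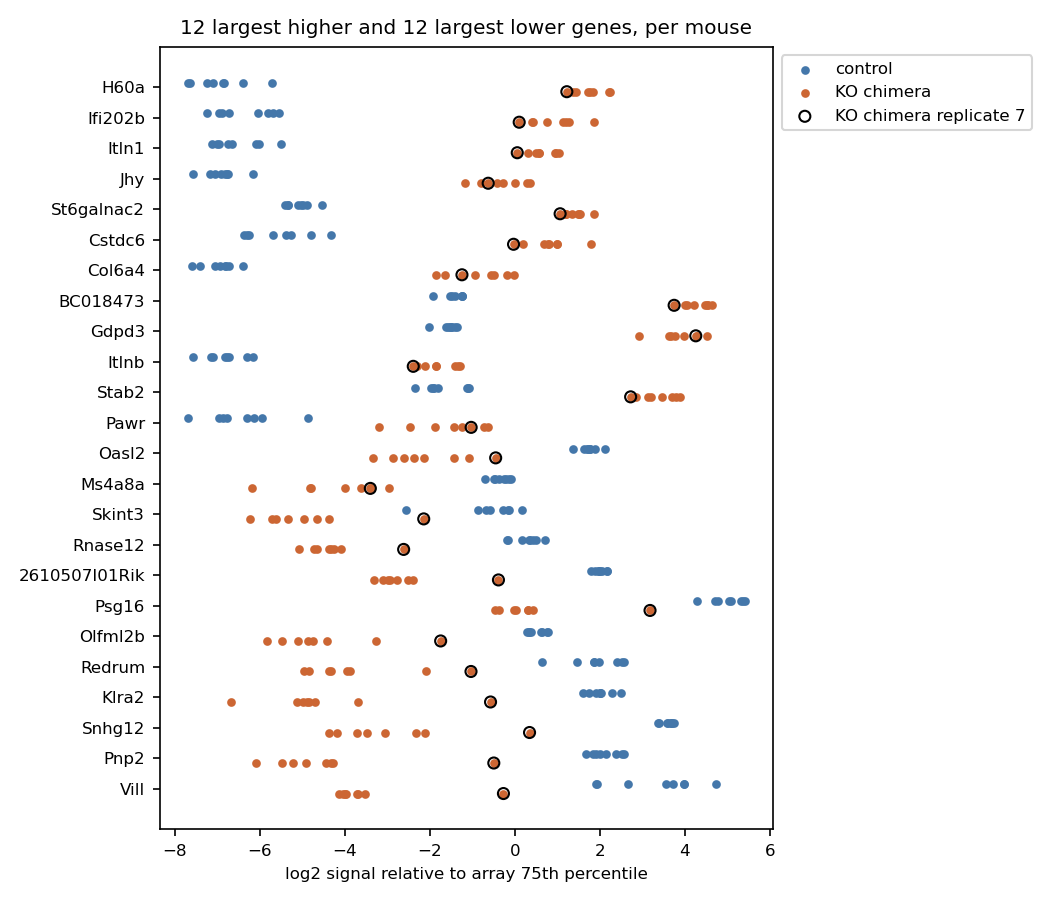
Signal of the 12 genes with the largest increases and the 12 with the largest decreases (vertical axis) in each of 16 mice, as log2 relative to the array's 75th percentile (horizontal axis), with controls in blue, KO chimeras in orange and KO chimera 7 circled. H60a is at least 107-fold higher and Vill differs by -6.72, and the circled mouse lies nearest to the controls for Vill and Pnp2.

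Lists of inflammatory, immediate early and heat shock, p53 target and monocyte genes shifted higher in the KO chimeras under camera at the preset correlation. Of the inflammatory cytokine and NF-kB target list, 11 of 19 measured members rose, 0 fell and 8 did not pass (14 up and 0 down adjusted over the list alone). The inflammatory median was 0.71 (camera adjusted p = 3.57e-07, adjusted p = 0.386 with an estimated correlation). The neutrophil chemokine Cxcl1 rose by 4.19 ± 0.44 (above background on 2 control arrays, so approximate), Tnfaip3, a feedback inhibitor of NF-kB, by 2.03 ± 0.22 and the monocyte chemokine Ccl2 by 1.43 ± 0.18 (adjusted p = 2.39e-06, 3.24e-06 and 2.38e-05). Of the immediate early and heat shock genes, 7 of 18 measured members rose, 0 fell and 11 did not pass (10 up and 0 down adjusted over the list alone). The immediate early median was 0.37 (camera adjusted p = 4.33e-06, adjusted p = 0.386 with an estimated correlation). Log2 differences included Ier2 at 1.22 ± 0.11, Atf3 at 1.44 ± 0.17 and Dusp1 at 0.81 ± 0.11. Of the p53 targets, 6 of 13 measured members rose, 0 fell and 7 did not pass (6 up and 1 down adjusted over the list alone). The p53 target median was 0.17 (camera adjusted p = 0.0271, adjusted p = 0.386 with an estimated correlation). Phlda3 rose by 2.07 ± 0.24, the pro-apoptotic gene Bbc3 by 1.28 ± 0.14 and Mdm2 by 0.49 ± 0.09. Of the monocyte markers, 4 of 13 measured members rose, 0 fell and 9 did not pass (4 up and 1 down adjusted over the list alone). The monocyte median was 0.13 (camera adjusted p = 0.0434, adjusted p = 0.825 with an estimated correlation). Log2 differences included the lipopolysaccharide co-receptor Cd14 at 2.26 ± 0.13, Klf4 at 0.71 ± 0.15 and Nr4a1 at 0.58 ± 0.15.

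The list of megakaryocyte and platelet markers shifted lower under the same test. Of this list, 1 of 15 measured members rose, 11 fell and 3 did not pass (1 up and 12 down adjusted over the list alone). The megakaryocyte median was -1.03 (camera adjusted p = 8.51e-07, adjusted p = 0.386 with an estimated correlation). The platelet receptor gene Clec1b differed by -2.87 ± 0.22, the integrin gene Itgb3 by -1.57 ± 0.12 and Gp1ba by -1.30 ± 0.19 (adjusted p = 5.62e-08, 3.67e-08 and 7.66e-05). Dimmer probes gave -0.76 and -2.87 for Clec1b and -0.57 for Itgb3. Of the T cell markers, 1 of 16 measured members rose, 9 fell and 6 did not pass (1 up and 10 down adjusted over the list alone). The T cell median was -0.38 (camera adjusted p = 0.00264, adjusted p = 0.52 with an estimated correlation). Thy1 differed by -1.20 ± 0.16 and Cd8a by -1.42 ± 0.19 (only -0.44 on a second probe, which did not pass), but Cd3d, a chain of the T cell receptor complex, rose by 2.18 ± 0.11. Of the interferon response genes, 0 of 20 measured members rose, 10 fell and 10 did not pass (0 up and 10 down adjusted over the list alone). The interferon median was -0.49 (camera adjusted p = 0.00241, adjusted p = 0.52 with an estimated correlation). Log2 differences included Ifit3 at -1.61 ± 0.23 beside Oasl2 above. Xaf1 read -1.40 ± 0.19 on its brightest probe but 3.83 on another, so its direction is not settled, though it is counted above as fallen; the mean of its probes gave 1.21.

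Lists of resident macrophage and dendritic cell markers also shifted lower under this test, with part of their members past the threshold. Of the macrophage list, 0 of 13 measured members rose, 6 fell and 7 did not pass (0 up and 6 down adjusted over the list alone). The macrophage median was -0.40 (camera adjusted p = 0.012, adjusted p = 0.52 with an estimated correlation). Log2 differences included Cd5l at -1.50 ± 0.21, the complement gene C1qc at -1.58 ± 0.30 and the receptor kinase gene Axl at -1.13 ± 0.21. Of the dendritic cell list, 0 of 11 measured members rose, 6 fell and 5 did not pass (0 up and 6 down adjusted over the list alone). The dendritic cell median was -0.42 (camera adjusted p = 0.012, adjusted p = 0.386 with an estimated correlation). Log2 differences included Clec9a at -1.56 ± 0.15, Ccr9 at -0.71 ± 0.15 and Batf3 at -0.59 ± 0.14. Of the eosinophil, basophil and mast cell list, 0 of 15 measured members rose, 5 fell and 10 did not pass (0 up and 5 down adjusted over the list alone). The granulocyte and mast cell median was -0.49 (camera adjusted p = 0.012, adjusted p = 0.539 with an estimated correlation). The histamine-synthesising enzyme gene Hdc differed by -1.29 ± 0.12, Prss34 by -0.49 ± 0.12 and Fcer1a by -0.46 ± 0.13. Of the osteoclast list, 0 of 10 measured members rose, 4 fell and 6 did not pass (0 up and 4 down adjusted over the list alone). The osteoclast median was -0.46 (camera adjusted p = 0.0268, adjusted p = 0.386 with an estimated correlation). Log2 differences included Ckb at -0.93 ± 0.17 and the collagen-degrading protease gene Ctsk at -1.44 ± 0.33. Itgb3 (-1.57), given above with the megakaryocyte list, is also a member here. Across all lists 7 genes are in more than 1 list, so the lists are not fully separate. With genes below background at their bound the osteoclast median was -0.24.

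None of the 12 list calls held with an estimated correlation. At the preset correlation, 3 of them also rested on single mice, slide or scan day. The monocyte call ended (adjusted p in brackets) without control 1 (0.0759), control 2 (0.0558), control 4 (0.0564), KO chimera 1 (0.135), KO chimera 2 (0.106), KO chimera 4 (0.0742), KO chimera 6 (0.0689), the adrenergic receptor call without control 1 (0.0505), control 4 (0.0564), KO chimera 1 (0.0791), KO chimera 2 (0.0609), KO chimera 5 (0.0547), and the p53 target call without control 8 (0.0517), KO chimera 4 (0.0504). With slide as a block the monocyte list had an adjusted p of 0.0946 and the receptor list 0.0528, and the other 10 lists stayed under 0.05. Within scan day 2 the monocyte, p53 target and receptor lists had adjusted p of 0.176, 0.0728 and 0.0504, and within scan day 1 the receptor list had 0.0771. Within the 5 slides holding both groups the inflammatory median ran from 0.38 to 1.17, the immediate early from 0.18 to 0.94, the p53 target from -0.0022 to 0.36, the monocyte from -0.089 to 0.39 and the receptor from 0.31 to 0.52. The megakaryocyte median ran from -1.46 to -0.16, the T cell from -0.51 to -0.19, the interferon from -0.86 to -0.36 and the macrophage from -0.70 to -0.29. The dendritic cell median ran from -0.48 to -0.42, the osteoclast from -0.46 to -0.29 and that of eosinophils, basophils and mast cells from -0.89 to 0.40.

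In all, 12 of the 32 lists shifted under camera with a preset correlation of 0.01, 5 higher and 7 lower, and 0 with an estimated correlation, where 2 lists had an unadjusted p under 0.05. By fry, which does not set a list against other genes, 18 lists shifted, these 12 in the same direction and further ones. Of the further lists, stem and progenitor cells (fry adjusted p = 0.046), plasma cells (0.0044) and NK and cytotoxic cells (0.0439) were lower. Endothelial cells (0.0333), skeletal muscle (0.0314) and strain-dependent genes (0.00188) were called higher. The medians of endothelial cells (-0.12) and strain-dependent genes (-0.48) were nevertheless negative. Of 100 splits of the 16 mice into groups of 8, 12 gave as many shifted lists, the real one included, so the list calls are weaker evidence than the gene calls.

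**Figure D3:**
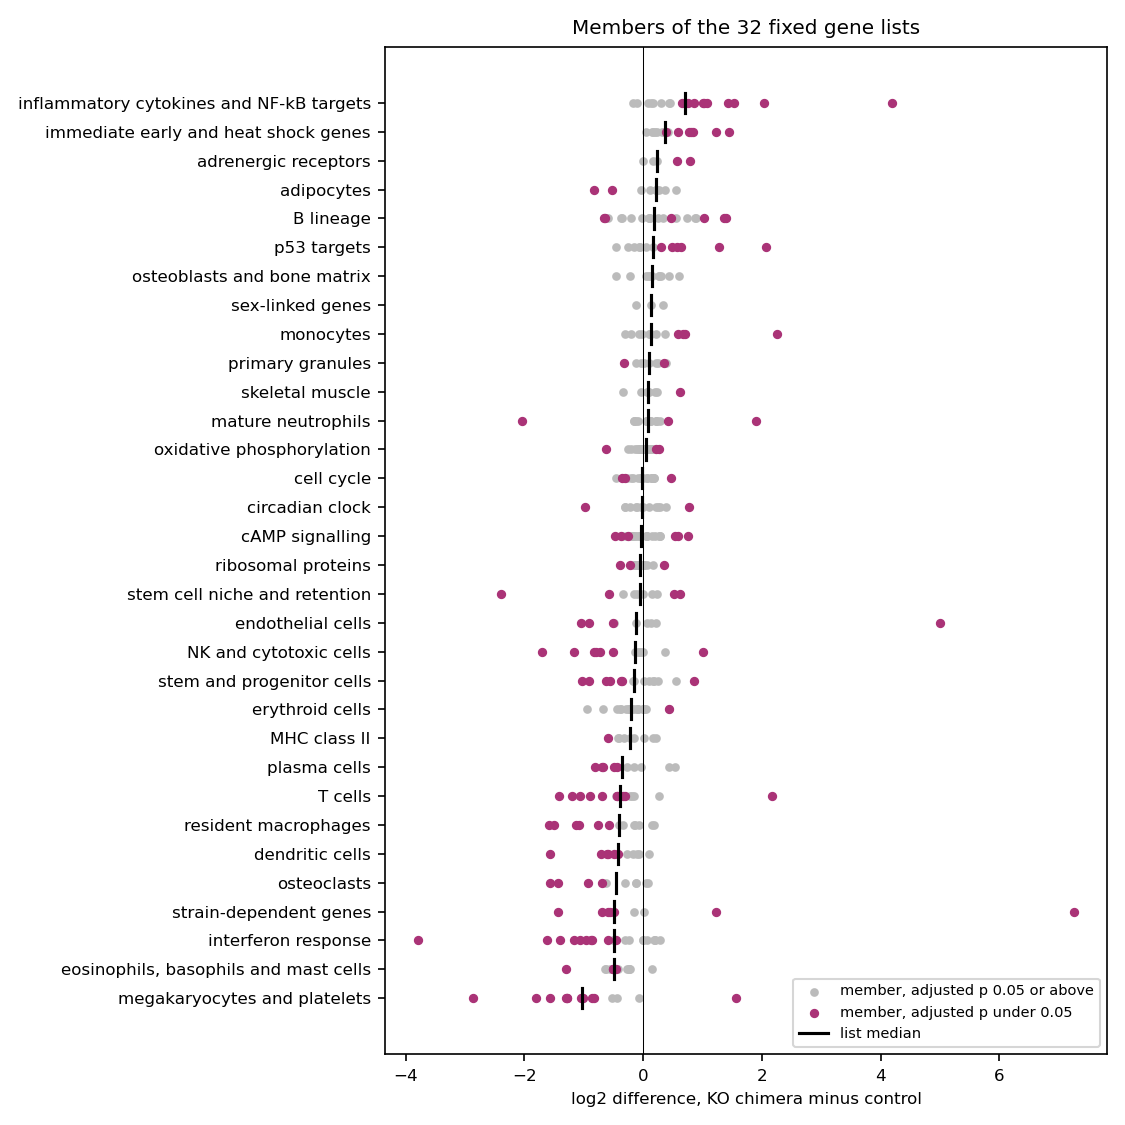
Log2 difference (KO chimera minus control, horizontal axis) of each measured member of the 32 gene lists (vertical axis, ordered by median), with members at adjusted p under 0.05 in purple, other members in grey and the list median as a black line. Medians run from -1.03 for megakaryocytes and platelets to 0.71 for inflammatory cytokines and NF-kB targets.

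Under camera, stem and progenitor genes did not shift as a list (median -0.15, camera adjusted p = 0.377). Of these genes, 1 rose and 6 fell of 15 measured (3 and 6 adjusted over the list alone). The stem cell factor receptor gene Kit differed by -0.90 ± 0.09, Meis1 by -0.63 and Gata2 by -0.56. Niche and retention genes did not shift either (median -0.054, camera adjusted p = 0.977). In that list 2 rose and 2 fell of 10 measured (2 and 2 adjusted over the list alone). The chemokine receptor gene Cxcr4 rose by 0.53 ± 0.09. Itga4 read -2.40 on one probe and 0.00099 on another, and Vcam1 read -0.58 and 0.24. Genes of cAMP signalling, the pathway downstream of beta receptors, went both ways (median -0.034, camera adjusted p = 0.977). Among them 3 rose and 3 fell of 27 measured (4 and 4 adjusted over the list alone), with log2 differences of Pde4a -0.47, Rgs2 0.54 and Adcy9 -0.38. Circadian clock genes did not shift (median -0.015, camera adjusted p = 0.977). There 1 rose and 1 fell of 14 measured (1 and 1 adjusted over the list alone). Bhlhe40 differed by 0.78, and Per1 by -0.98 on one probe and 0.40 on another.

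Lists of primary granules and mature neutrophils did not shift. For primary granules (median 0.11, camera adjusted p = 0.547) 1 rose and 1 fell of 9 measured (1 and 1 adjusted over the list alone). For mature neutrophils (median 0.087, camera adjusted p = 0.474) 2 rose and 1 fell of 20 measured (2 and 1 adjusted over the list alone). Their changed members went both ways, with log2 differences of Cebpe -0.33, Ctsg 0.34, Itgb2l -2.05, Olfm4 1.90 and Anxa1 0.42. Ctsg lost its call without control 1, 2, 3, 4, 6 or 7 or without KO chimera 1, 2, 4 or 6 (adjusted p 0.0517 to 0.081). In the B lineage (median 0.18, camera adjusted p = 0.46) 4 rose and 2 fell of 20 measured (4 and 2 adjusted over the list alone). Log2 differences there were Bank1 -0.65, Cr2 -0.65 and Vpreb1 1.36. Plasma cell genes did not pass as a list (median -0.35, camera adjusted p = 0.0772), and 0 rose and 5 fell of 10 measured (1 and 5 adjusted over the list alone). Jchain (Igj on the array) differed by -0.81, Tnfrsf17 by -0.68 and Xbp1 by -0.44. NK and cytotoxic genes did not pass either (median -0.14, camera adjusted p = 0.0802), and 1 rose and 6 fell of 13 measured (2 and 6 adjusted over the list alone). Examples were Ncr1 1.00, Klrk1 -1.70 and Klra8 -1.17, the size for Klrk1 being approximate, as it was above background on 2 KO chimera arrays. Among erythroid genes (median -0.20, camera adjusted p = 0.846) 1 rose and 0 fell of 21 measured (1 and 0 adjusted over the list alone), and Hemgn rose by 0.44. Among MHC class II genes (median -0.22, camera adjusted p = 0.384) 0 rose and 1 fell of 9 measured (0 and 1 adjusted over the list alone), and Ciita differed by -0.60.

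On their brightest probes, osteoblast and bone matrix genes held no changed member under limma (median 0.15, camera adjusted p = 0.581, 0 rose and 0 fell of 11 measured (0 and 0 adjusted over the list alone)). Their smallest p belonged to Ibsp (0.61, adjusted p = 0.121) and Mepe (-0.22, adjusted p = 0.171), which did not pass; a second Ibsp probe read 0.73 and passed over all probes (adjusted p = 0.039). Among adipocyte genes (median 0.22, camera adjusted p = 0.581) 0 rose and 2 fell of 10 measured (0 and 2 adjusted over the list alone). Scd1 differed by -0.52 and Cd36 by -0.83, although the list's median was positive. Scd1 lost its call without control 1, 2, 4 or 6 or without KO chimera 3, 4 or 6 (adjusted p 0.0542 to 0.0653). Cd36 lost its call without control 1, 2, 3 or 4 or without KO chimera 1, 2, 4, 5 or 6 (adjusted p 0.0569 to 0.0778). Among endothelial genes (median -0.12, camera adjusted p = 0.977) 1 rose and 3 fell of 9 measured (1 and 3 adjusted over the list alone). Cdh5 differed by -0.91 and Flt1 by -0.50, and with Stab2 included the list's mean was 0.26. Among skeletal muscle genes (median 0.088, camera adjusted p = 0.402) 1 rose and 0 fell of 8 measured (1 and 0 adjusted over the list alone), and Pvalb rose by 0.62. Among cell cycle genes (median -0.012, camera adjusted p = 0.977) 1 rose and 2 fell of 20 measured (0 and 0 adjusted over the list alone), with Top2a -0.30, Aurka -0.35 and Rrm2 0.47. Aurka lost its call without control 1, 2, 3, 4, 5, 6 or 7 or without KO chimera 1, 2, 3 or 5 (adjusted p 0.054 to 0.0807). Rrm2 lost its call without control 1, 3, 4, 5, 6, 7 or 8 or without KO chimera 3, 4, 5, 6, 7 or 8 (adjusted p 0.0511 to 0.0829). Among ribosomal protein genes (median -0.052, camera adjusted p = 0.458) 1 rose and 2 fell of 25 measured (1 and 2 adjusted over the list alone). Rps19 differed by -0.23, while Rplp1 read -0.40 and 0.21 on 2 probes and Rps2 read 0.36 and -0.67. Rps19 lost its call without control 2, 3, 4 or 6 or without KO chimera 3 (adjusted p 0.05 to 0.0608). Among oxidative phosphorylation genes (median 0.049, camera adjusted p = 0.547) 2 rose and 1 fell of 25 measured (2 and 1 adjusted over the list alone), with Cox5b -0.62 and Cox5a 0.27.

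Genes known to differ between mouse strains changed more often than not. Of this list, 2 of 9 measured members rose, 5 fell and 2 did not pass (2 up and 5 down adjusted over the list alone), while the list as a whole did not shift in one direction under camera (median -0.48, mean 0.51, camera adjusted p = 0.846). Nnt, a mitochondrial transhydrogenase gene that is truncated in C57BL/6J, rose by 1.24 ± 0.09 on its brightest probe and by 0.79 and 0.16 on dimmer ones (exact two-sided permutation p = 0.0535 and 0.273). Entpd4 differed by -0.58, Ide by -0.57 and Klrd1 by -0.48, while a second Entpd4 probe read -0.066 and did not pass. Klrd1 lost its call without control 2, 3, 4, 5, 7 or 8 or without KO chimera 1, 2, 5, 6, 7 or 8 (adjusted p 0.051 to 0.076). Gpnmb was at least 1.42-fold lower, above background on 6 control arrays and 0 KO chimera arrays. Wdfy1 read -0.68 on its brightest probe (adjusted p = 0.0499) but -0.45, 0.37 and 0.95 on others, so its direction is not settled, though it is counted above as fallen. Wdfy1 lost its call without control 1, 2, 4, 5, 6 or 7 or without KO chimera 2, 3, 4, 5, 6, 7 or 8 (adjusted p 0.0542 to 0.0897). Alad (-0.16, adjusted p = 0.793) and Glo1 (0.013, adjusted p = 0.969) did not pass. Of the sex-linked genes, 0 of 3 measured members rose, 0 fell and 3 did not pass (0 up and 0 down adjusted over the list alone) (median 0.14, camera adjusted p = 0.846), with Ddx3y at 0.14, Eif2s3y at -0.13 and Uty at 0.33 (adjusted p = 0.655, 0.703 and 0.553).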

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

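The tests of probes unplaced on mm9, of marker medians and of KO chimera 7 were chosen only after the results were seen, and the fit with array brightness was added later; the tests of second probes and of other splits were set beforehand. Of 290 sets of values in a group, 27 had a mouse far from the others, where chance gives about 14.5 (1 in 20).

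The first pattern is the 5140 changed genes. Of 100 splits of the 16 mice, 1 gave as many, the real one, and the highest other gave 1122. That other split placed 7 mice of each group as in the labels. The splits argue against chance, though 100 of them cannot show a share below 1 in 100. The array's brightness left 4645 changed genes as a covariate, 4298 of them shared. Of 1164 changed genes past 1 (log2), 208 had a second kept probe, and 67.3% of these probes moved the same way. For these 208 genes, sequence differences under single probes do not account for the whole. Still, 53 second probes did not move, 15 moved the opposite way and 94 had under 0.5 times the log2 difference, so single genes may be affected. The other changed genes were not tested in this way. A donor genome other than C57BL/6J may contribute: 8 of 213 genes with probes unplaced on mm9 rose by more than 2, a share 8.85 times that of placed probes (Fisher's exact p = 6.01e-06), against 2.46 times for genes that fell (p = 0.128). Loss of the receptors and grafting itself stay open and untested, because the labels give the knockout to every KO chimera and name no donor for the controls, and the genetic background of the donors is not given in the sources used here.

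The second pattern is the higher inflammatory and immediate early lists. The inflammatory list's median of 0.71 exceeded the 0.13 of 13 monocyte markers (95% bootstrap interval -0.017 to 0.58, permutation p = 0.0199). It also exceeded the 0.087 of 20 neutrophil markers (0.055 to 0.17, permutation p = 3.30e-04). The immediate early median of 0.37 exceeded them with permutation p = 0.0507 for monocyte and 2.70e-04 for neutrophil markers. Both resamplings took genes as independent and did not resample mice. Members of a list vary together, with an estimated correlation of 0.44 for the inflammatory and 0.59 for the monocyte list. More monocytes or neutrophils therefore stay open for both lists. Lower signal on the KO chimera arrays is argued against at the preset correlation, where both lists kept a camera adjusted p of 1.39e-05 or less with brightness as a covariate. With an estimated correlation neither list passed even without the covariate (camera adjusted p = 0.386 for each). Chance is not excluded for the number of shifted lists: 12 of 100 splits gave as many as the real 12, and the highest other gave 16. Tissue handling, grafting, donor strain and receptor loss stay open, and no label gives a collection time.

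The third pattern is KO chimera 7, whose values lay above the other KO chimeras for Vill (-0.27), Pnp2 (-0.49), Psg16 (3.18), 2610507I01Rik (-0.39), Rnase12 (-2.62) and Skint3 (-2.14). A single wrong label is argued against, since 93.8% (15 of 16) of transcripts found in the other KO chimeras and not in controls were above background in this mouse. Remaining C57BL/6J cells or RNA may contribute but stay open: over 19 control-type genes chosen without this mouse, its median was 15% of the control level, above 3.58% to 12.3% in the others, but 68.4% of its genes exceeded the highest of these, short of the 75% set for this explanation. In each of the others only 0 to 3 of 12 to 16 such genes were above background, so their shares are approximate. The highest of the others, KO chimera 2, had 0 of 16 such genes above background, and KO chimera 7 had 10 of 19. KO chimera 2 had the dimmest array (75th percentile 127) and KO chimera 7 the brightest of the KO chimeras (545), so this contrast follows brightness in part. KO chimeras 5 and 8, at 427 and 468, had 3 of 15 and 2 of 14.

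Other mice far from the rest of their group, with the log2 value that stood apart, are given without explanation. Control 4 stood apart for BC018473 (lowest, -1.92) and the median of circadian clock (highest, -0.071). Control 1 stood apart for Gdpd3 (lowest, -2.02). Control 3 stood apart for Skint3 (lowest, -2.57) and Vpreb1 (lowest, 0.28). Control 8 stood apart for Bhlhe40 (lowest, -0.10). Control 2 stood apart for Meis1 (lowest, -0.64), Batf3 (lowest, -1.84), Ckb (lowest, -1.71), the median of cAMP signalling (highest, 1.43) and the median of stem and progenitor cells (lowest, -0.64). Control 5 stood apart for Rps2 (lowest, 6.92) and Alad (lowest, 1.96). KO chimera 4 stood apart for Anxa1 (lowest, 7.77). KO chimera 6 stood apart for Hemgn (lowest, 5.73), Fcer1a (lowest, 0.65) and Entpd4 (highest, 1.44). KO chimera 5 stood apart for Ddx3y (lowest, 0.28), Eif2s3y (lowest, 1.74), Gpnmb (lowest, -6.95) and the median of sex-linked genes (lowest, 0.28).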

How the results depend on the processing

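Fits within a scan day and with array brightness were chosen after seeing the data. Over the settings with all genes refitted, other than the fits within a scan day, 4384 to 6470 genes changed, against 5140; leaving out a mouse gave 4392 to 5325. Signal over background limits the lowest genes. As replicate numbers did not pair the mice (correlation of deviations -0.19 to 0.20, and 0 controls matched their own number best), the replicate block gave 4726 changed genes, 2174 higher and 2552 lower. No spot was saturated, so leaving out saturated probes was void. The fits within a scan day had 4 mice per group, and an unadjusted threshold counts more genes by construction; for the other values below the cause was not tested. Values are log2 differences for genes and medians, adjusted p for lists, and counts otherwise; of the 93 tested sign changes 88 concern genes or lists past the threshold under neither setting. Under normexp with quantile: cAMP signalling list 0.92. Under no filter on dim probes: stem cell niche and retention list 0.757, cell cycle list 0.728, sex-linked genes list 0.728. Under above background on all arrays: endothelial cells list 0.593, cell cycle list 0.917. Under slide as a fixed block: B lineage list 0.998. Under slide as a random block: Adrb1 0.00040. Under replicate block: cAMP signalling list 0.965, circadian clock list 0.965, cell cycle list 0.965. Under mean of all kept probes: Adrb1 0.47, Xaf1 1.21, Rps2 -0.16, Uty -0.11, Wdfy1 0.048, cAMP signalling list 0.395, circadian clock list 0.796, stem cell niche and retention list 0.942, endothelial cells list 0.984, sex-linked genes list 0.984, strain-dependent genes list 0.942. Under one test per probe: cAMP signalling list 0.441, circadian clock list 0.939, stem cell niche and retention list 0.824, endothelial cells list 0.284, sex-linked genes list 0.926, strain-dependent genes list 0.294. Under array weights: Adrb1 0.080, Uty -0.0060, Ddx3y -0.055, Alad 0.044, erythroid cells list 0.525, sex-linked genes list 0.853. Under array brightness as a covariate: Adrb1 0.017, Alad 0.083, erythroid cells list 0.706, endothelial cells list 0.941. Within scan day 1: genes changed 1612, genes higher 699, genes lower 913, Eif2s3y 0.076, Glo1 -0.00026, B lineage list 0.99, adipocytes list 0.996, cell cycle list 0.924. Within scan day 2: genes changed 2314, genes higher 1218, genes lower 1096, Adrb1 0.13, Ddx3y -0.010, cAMP signalling list 0.947, circadian clock list 0.85, stem cell niche and retention list 0.947, sex-linked genes list 0.931. Under camera with an estimated correlation: gene lists shifted 0. Under fry: endothelial cells list 0.0333, cell cycle list 0.885, strain-dependent genes list 0.00188. Under unadjusted p under 0.05: genes changed 7815, genes higher 3642, genes lower 4173. Within slide 1: Prss34 0.039, eosinophils, basophils and mast cells list median 0.40, p53 targets list median -0.0022. Within slide 2: Cd36 0.20, monocytes list median -0.089. Within slide 5: Adrb1 -0.33, Adcy9 0.0070, Vpreb1 -0.32. Of 102 named genes called, 94 were called whichever mouse was left out; Aurka, Cd36, Ctsg, Klrd1, Rps19, Rrm2, Scd1, Wdfy1 were not (adjusted p up to 0.0897). Leaving out a mouse turned a sign over these ranges: circadian clock list 0.767 to 0.995, endothelial cells list 0.84 to 0.995, cAMP signalling list 0.917 to 0.994, erythroid cells list 0.344 to 0.994, Glo1 -0.049 to 0.12, cell cycle list 0.516 to 0.994, Adrb1 -0.043 to 0.071, stem cell niche and retention list 0.721 to 0.999, Alad -0.32 to 0.047, Eif2s3y -0.20 to 0.069.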

Other observations

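Each mouse was also read for transcripts typical of the other group, chosen without that mouse; apart from the splits, the tests in this part were chosen after the results were seen. Over 12 to 19 control-type genes per mouse, KO chimeras had a median of 3.58% to 15% of the control level. These shares are approximate, as only 0 to 3 such genes were above background in each KO chimera other than number 7, which had 10. Over 13 to 16 KO-type genes per mouse, the median was 65.6% of the level of the other KO chimeras in KO chimera 7 and 95.6% to 128% in the rest. Controls had 1.12% to 3.31% of the KO chimera level of such genes. In each control only 0 to 2 of 13 to 15 of them were above background, so these shares are approximate.

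The labels give a ratio of 1:4 for knockout to C57BL/6J, and one hypothesis is that the graft mixed 1 part knockout with 4 parts C57BL/6J marrow. If the 2 kinds of marrow simply added up, each control transcript would keep most of its level, but 70 of 18245 genes above background on all arrays were lower by more than 1 on the log2 scale (limma treat, adjusted p under 0.05). This argues against such a sum in the harvested marrow. Of the strain-dependent genes, 7 of 9 changed, against 22.3% of other genes (two-sided Fisher's exact p = 6.37e-04). Among these 7, Wdfy1 lost its call without any 1 of 13 mice and Klrd1 without any 1 of 12. Probes of Wdfy1 also went both ways. Nnt, Ifi202b, Entpd4, Ide and Gpnmb were called whichever mouse was left out.

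For single lists, the number of the 100 splits with a camera p as small as the real one, the real one included, was 2 for p53 targets, 4 for inflammatory cytokines and NF-kB targets, 6 for immediate early and heat shock genes, 6 for megakaryocytes and platelets, 8 for osteoclasts, 10 for dendritic cells, 10 for adrenergic receptors, 14 for T cells, 20 for interferon response, 24 for resident macrophages, 28 for eosinophils, basophils and mast cells and 36 for monocytes.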
